A study of Mus musculus with 4 samples.

How the data were processed

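Gene expression was measured by RNA sequencing in 4 cultures of mouse glioma initiating cells, for which the labels give the subventricular zone of the adult brain as the source, grown in DMEM/F12 medium with B27, EGF and FGF. Per the labels, the animals had a mixed C57BL/6 and FVB background. Both lines of one genotype lacked Pten and p53 and carried wild-type Idh1 (Pten/p53), and both lines of the other also carried the R132H form of Idh1 (Idh1/Pten/p53). The series description speaks of 2 lines per genotype, while the sample titles give 1 letter per genotype (A and F) with the numbers 1 and 2. The 2 libraries of a genotype may therefore be cultures of 1 line, and no source says whether they came from separate animals. With Spearman correlations of 0.996 and 0.998 within a genotype, p-values measure only the spread between these libraries, which may be partly technical. They are called lines in the text, after the series description. Per the labels' protocols, total RNA was extracted with a column kit and standard Illumina libraries were made. Strand use in library making and counting is not given in the sources used here, so a gene and an overlapping or antisense partner cannot be separated.

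The submitters' processing notes name TopHat2, Picard 1.72, HTSeq and DESeq with the mm10 genome, without saying which step each served. Each deposited file gives 1 signal value per gene for 20368 genes, and the unit is not given in the sources used here. The values follow a simple rule in each library. Every deposited value can be written as a whole number of reads, multiplied by a number specific to the gene and by a step specific to the library. The gene number behaves roughly like a transcript length: it had a median of 0.98 of the longest annotated transcript over 12959 genes with at least 40 reads. It lay within 10% of that transcript for 61.4% of these genes and equalled an annotated length for 16.1%. A number well above that transcript was divided by the factor that brought it closest, so part of the match is built in. All nonzero values were whole multiples of the library step within 0.2 of a step (100%, largest deviation 0.186). The gene number was taken as a common divisor over the 4 libraries, so the read numbers are whole by construction. Recovery was exact for simulated genes, whose reference lengths lay closer to the true ones than can be assumed for real genes. That result therefore does not show that every real read number is exact. A read number shared by all 4 libraries as a common factor cannot be seen in this way. Such a factor over 1 occurred in 7.1% of the genes, against 7.6% for random numbers.

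The library step rises with depth: relative to their mean the steps were 0.846, 0.901, 1.135 and 1.156 and the recovered read totals 0.852, 0.899, 1.127 and 1.157. The deposited values are therefore not corrected for depth. Their sums differed 1.71 times between the genotypes, against 1.3 times for the reads. The recovered totals were 32575544 and 34377945 reads in the Idh1/Pten/p53 libraries and 43094536 and 44241415 in the Pten/p53 libraries. Since the read totals are reconstructed rather than given, the main test ran on the deposited signal values and the recovered reads served for depth, the filter on low genes and levels.

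The deposited values were rescaled between libraries with trimmed mean of M values factors (TMM, trimming 30% of the log ratios and 5% of the mean levels on each side). They were then tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust empirical Bayes estimation through statmod 1.5.0 and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05. A gene was tested when it reached the equivalent of 10 reads at the median library size (0.26 CPM) in at least 2 libraries and 15 reads in all, which left 13265 genes. Fold changes are Idh1/Pten/p53 minus Pten/p53 on the log2(value + 1) scale. The pseudocount of 1 equals about 13 reads for a gene of median length, so these values understate the change of low genes. Levels are the recovered reads as CPM, computed with TMM-scaled library sizes, given as mean ± SD of 2 libraries, and plain folds are ratios of these means. For genes with at most 3 reads in a genotype, the ratio is given with an exact 95% counting interval. For genes with 0 reads the fold is a lower bound against a floor of 3 reads over the 2 libraries. Both cover counting error only, and the reads carry no molecular identifiers.

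A count model had been planned before the data were examined, on the expectation of whole counts. The planned substitute for normalized values, limma on log2(value + 1), took its place. The 39 gene lists were fixed before the data were examined. The 33 with at least 5 tested members, leaving out the sex-linked, mitochondrial and haemoglobin lists, were tested with camera in limma on the same log2 values, at a preset correlation of 0.01 and with adjustment over the 33 lists. Camera on voom values, which had been planned as the main input, was run on the recovered reads as an alternative. Named genes were chosen by a rule, also fixed before: Idh1, Pten and Trp53; the 12 genes with the largest change in each direction among called genes with a mean of at least 5 CPM and no overlap between the genotypes; and up to 4 members of each list with the lowest adjusted p, with up to 2 more of high mean CPM for a called list. Clone and model names were left out. Members of these sets are named where they serve the text, and genes chosen after their values were seen are marked as such.

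Symbols altered by a spreadsheet (26) were restored through the gene identifiers, and 20028 of the 20368 identifiers matched GENCODE M21 on the mm10 assembly, from which positions were taken. Xist, Tsix and the mitochondrial transcripts are not among the genes analysed here. Reads shared between near-identical copies, as for ribosomal protein and major histocompatibility genes, cannot be assigned with certainty at the gene level.

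On simulated reads for the 13265 genes of this comparison, with 50 changed genes of each size at the depths seen here and a coefficient of variation of 10% beyond counting, the procedure found 16% of changes of 0.5 on the log2 scale and 100% of those of 1, 2 and 4, with 5 false calls. The changed genes were drawn only from genes with more reads than the filter requires, so recovery of the lowest genes was not tested. The libraries themselves varied by 7.6% (Idh1/Pten/p53) and 3.2% (Pten/p53), so the recovery above is for a wider spread than seen here. The simulation also changed few genes, balanced between the directions, whereas 71.6% of the real genes were called. It therefore does not test the rescaling or the false calls in that state. Alternatives covered other scalings, filters, thresholds, tools that accept normalized values, a replicate block, leaving out each library, and, added after the data were seen, other pseudocounts, the deposited values without rescaling, thinned reads, another variance prior and leaving out chromosomes X and Y. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.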

Results

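RNA sequencing compared glioma initiating cells, cultured cells able to start a glioma, with and without a mutant Idh1. Idh1 encodes the cytosolic isocitrate dehydrogenase, and the R132H form found in human gliomas makes 2-hydroxyglutarate from 2-oxoglutarate. The Pten/p53 genotype (n = 2 libraries) lacked the tumour suppressors Pten and p53, and the Idh1/Pten/p53 genotype (n = 2 libraries) also carried mutant Idh1. The libraries held 32575544 and 34377945 recovered gene-assigned reads for the Idh1/Pten/p53 lines and 43094536 and 44241415 for the Pten/p53 lines, and 13265 genes were tested. Levels below are CPM (mean ± SD, n = 2) and SE belongs to the limma log2 fold change.

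The targeted genes were examined first. Idh1 (ENSMUSG00000025950, chromosome 1, 65158616 to 65186500, mm10) stood at 122 ± 0.742 CPM in the Idh1/Pten/p53 lines and at 294 ± 9.18 CPM in the Pten/p53 lines. This 2.41-fold lower level was a log2 fold change of -1.26 ± 0.07 (SE; limma, adjusted p = 1.49e-05). Pten (chromosome 19) stood at 81.0 ± 8.25 and 79.3 ± 2.9 CPM, a log2 difference of 0.04 ± 0.10 (limma, adjusted p = 0.737). Trp53, the p53 gene (chromosome 11), stood at 7.48 ± 1.14 and 8.66 ± 0.681 CPM, a log2 difference of -0.19 ± 0.14 (limma, adjusted p = 0.245). The direction for Pten was not settled, since it became -0.07 without Idh1/Pten/p53 replicate 2, and Trp53 reached -0.36 with an adjusted p of 0.0497 in limma without Idh1/Pten/p53 replicate 1. Gene totals cannot show the Idh1 point mutation, and the deleted exons of Pten and Trp53 are not given in the sources used here, so these levels do not check the deletions.

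The main comparison asked which genes differ between Idh1 mutant and wild-type glioma initiating cells. Most did: limma called 9503 of 13265 genes (71.6%), with 4647 higher and 4856 lower in the Idh1/Pten/p53 lines. A change of at least 2-fold was called for 3368 genes (1626 higher, 1742 lower), and of at least 8-fold for 416 (169 higher, 247 lower). Lines of one genotype were close to each other, with Spearman correlations across genes of 0.996 (Idh1/Pten/p53) and 0.998 (Pten/p53), against 0.911 to 0.916 between genotypes. The values of the genotypes did not overlap for 86.8% of the genes, where chance gives 33.3%. The first principal component held 97.0% of the variance and separated the genotypes. With the deposited values not rescaled, the median gene lay 0.74 lower on the log2 scale in the Idh1/Pten/p53 lines, and 1571 genes were called higher and 9167 lower (14.6% of calls higher, against 48.9% after rescaling). In those values depth enters through the reads and again through the library step, and their sums were 1.71 times larger for the Pten/p53 libraries. The shift of the median gene therefore largely reflects depth, and turns of direction without rescaling mostly restate it. Directions below are relative to the median gene. In 13 lists most called members were higher after rescaling and lower without it: ribosomal protein genes, which camera called, and the p53 target, neural stem cell, oligodendrocyte progenitor, oligodendrocyte, proneural, dioxygenase, DNA methylation, glutamate, Notch and Hedgehog, immediate early, receptor tyrosine kinase and PI3K lists, which it did not. The Y-linked genes also separated the genotypes (given last), so every difference below is one between these lines, which differ in more than the Idh1 label.

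**Figure D1:**
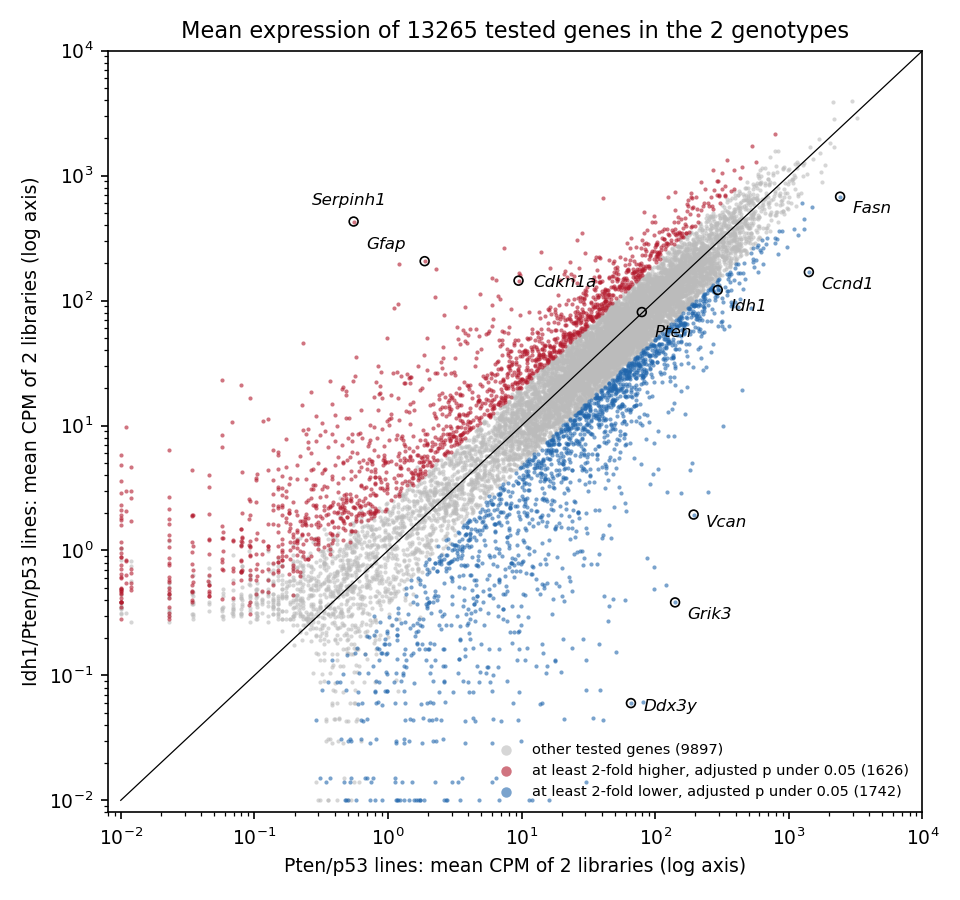
Mean CPM of each of the 13265 tested genes in the Pten/p53 lines (horizontal, log axis) and the Idh1/Pten/p53 lines (vertical, log axis), with means under 0.01 drawn at 0.01 and the diagonal marking equal levels. The 1626 genes called at least 2-fold higher are red and the 1742 called at least 2-fold lower are blue, and Serpinh1 and Grik3 lie far from the diagonal while Pten lies on it.

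Among the most changed genes, Serpinh1 (chromosome 7, 99345376 to 99353239), the collagen chaperone HSP47, rose 777-fold, from 0.553 ± 0.106 to 429 ± 18.4 CPM (log2 fold change 8.81 ± 0.11 SE; limma, adjusted p = 7.12e-07). Anxa6, a calcium-dependent membrane-binding annexin, rose 161-fold to 196 ± 43.7 CPM, and Gfap, the intermediate filament of astrocytes, rose 110-fold from 1.88 ± 0.687 to 207 ± 0.0600 CPM. Agt, which encodes angiotensinogen, and Dbx2, a homeobox factor of neural progenitors, rose 78.8-fold and 78.5-fold. By log2 fold change, on which this set was ranked, the others with the largest rises were Mybpc1, Serpinb1a, Tep1, Igf2bp3, Atp2a3, Otoa and Galm. Their log2 fold changes were 5.35 (Galm, SE 0.15) to 6.59 (Mybpc1, SE 0.11). Thy1 and Sp8, given below, had larger plain folds than several of these genes but smaller log2 fold changes. In the other direction, Grik3 (chromosome 4, 125490700 to 125714173), a kainate receptor subunit, fell 366-fold, from 141 ± 1.03 to 0.384 ± 0.110 CPM (log2 fold change -8.15 ± 0.15 SE; limma, adjusted p = 1.01e-06). Vcan, the matrix proteoglycan versican, fell 100-fold from 194 ± 6.91 to 1.94 ± 0.485 CPM, the phospholipid flippase gene Atp9a fell 231-fold, and the collagen gene Col19a1 fell 133-fold (99.5-fold and 199-fold with either Idh1/Pten/p53 line left out). Galnt13, a glycosyltransferase gene, had 1 read in the 2 Idh1/Pten/p53 libraries together against 2641 in the Pten/p53 libraries, a ratio of 2040 (95% exact counting interval 366 to 80700). That read lies in Idh1/Pten/p53 replicate 2: the ratio of mean CPM is 2100 with all libraries and 1050 without replicate 1, and without replicate 2 no read is left. Gabra3, a GABA receptor subunit gene, had 3 against 3531 reads, a ratio of 910 (interval 311 to 4410). Sorcs3 and Clmp, at 30.4 ± 1.29 and 38.8 ± 0.104 CPM in the Pten/p53 lines, were at 0.134 ± 0.0150 and 0.0760 ± 0.0660 CPM in the Idh1/Pten/p53 lines. The remaining genes of this set are Y-linked.

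Cell cycle genes were lower in the Idh1/Pten/p53 lines. All 27 tested members of the proliferation list fell, 19 of them at least 2-fold, both over all genes and adjusted over the list alone (camera, adjusted p = 2.7e-08; adjusted p = 0.471 with an estimated correlation). Ccnd1, the G1 cyclin D1, fell 8.34-fold, from 1411 ± 62.7 to 169 ± 5.25 CPM, and Ccne1, cyclin E1, fell 6.24-fold. The mitotic kinase gene Aurkb fell 4.36-fold, the ribonucleotide reductase gene Rrm2 3.99-fold, the proliferation marker gene Mki67 3.61-fold and the topoisomerase gene Top2a 2.01-fold. Of 23 DNA repair genes, 18 fell and 1 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.000807; adjusted p = 0.433 with an estimated correlation). Among them the mismatch repair genes Msh6 and Msh2 fell 2.79-fold and 1.73-fold, Parp1 2.48-fold, the recombinase gene Rad51 2.64-fold and the damage kinase gene Atm 2.09-fold. Mgmt, the member that rose and chosen after its value was seen, went from 1.49 ± 0.364 to 3.43 ± 0.127 CPM, and did not pass without rescaling (limma, adjusted p = 0.142). The CDK inhibitors and Rb family (4 higher, 5 lower of 10) and the p53 target genes (11 higher, 8 lower of 20) were not called by camera (adjusted p = 0.764 and 0.475), and these counts were the same adjusted over the list alone. Individual members still changed: Cdkn1a, the CDK inhibitor p21, rose 15.2-fold, from 9.48 ± 0.762 to 144 ± 14.9 CPM, and Cdkn1b, p27, rose 2.55-fold, while Rbl1 and Cdkn2a fell 2.02-fold and 1.74-fold. Of the other p53 targets, Fas rose 20.6-fold to 3.80 ± 0.469 CPM, while Plk2 and Aen fell 2.70-fold and 2.33-fold.

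**Figure D2:**
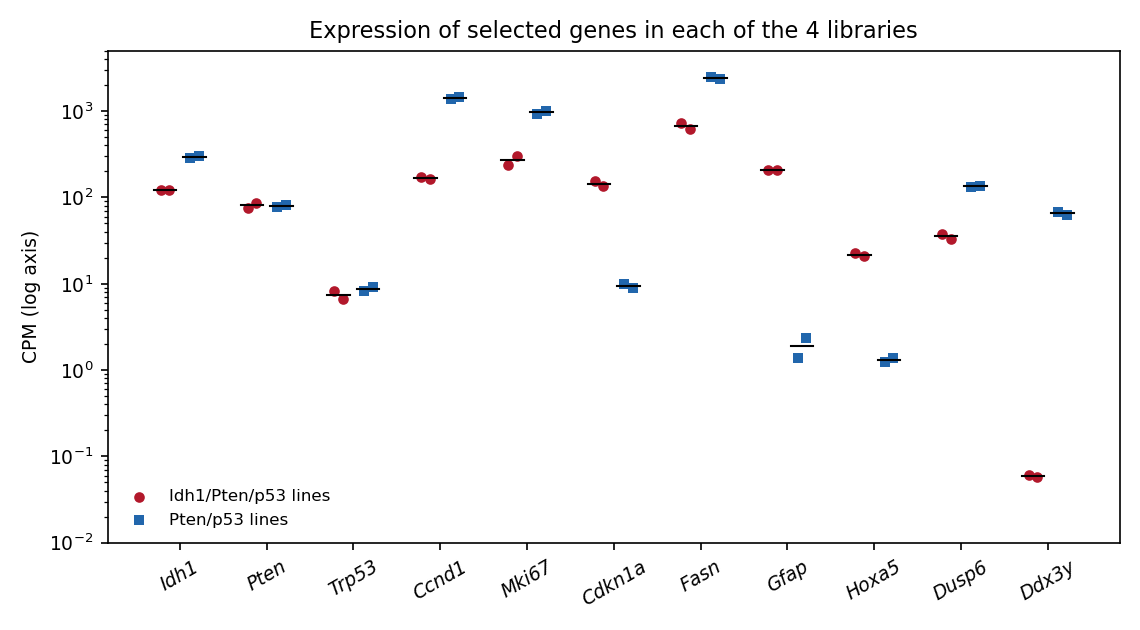
CPM (log axis) of 11 genes in each of the 4 libraries, with circles for the 2 Idh1/Pten/p53 lines, squares for the 2 Pten/p53 lines and bars for the means. The circles lie below the squares for Idh1, Ccnd1, Mki67, Fasn, Dusp6 and Ddx3y, above them for Cdkn1a, Gfap and Hoxa5, and close to them for Pten and Trp53.

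Astrocyte markers rose and neuronal markers fell. In the astrocyte list 12 of 17 tested members rose and 1 fell (13 and 1 adjusted over the list alone; camera, adjusted p = 0.00288; adjusted p = 0.453 with an estimated correlation). Besides Gfap, Aldh1l1, an astrocytic folate enzyme, rose 23-fold to 147 ± 18.3 CPM, the calcium-binding protein gene S100b 44.2-fold to 20.3 ± 3.24 CPM, and the glutamate transporter genes Slc1a2 and Slc1a3 2.74-fold and 1.76-fold, of which Slc1a3 did not pass without rescaling (limma, adjusted p = 0.761). Aldoc, the brain aldolase, rose 2.34-fold. In the neuron list 13 of 17 members fell and 3 rose, also adjusted over the list alone (camera, adjusted p = 0.0113; adjusted p = 0.466 with an estimated correlation). Elavl3 fell 6.58-fold, the neuroblast microtubule gene Dcx 6.45-fold and the transcription factor gene Neurod1 14.8-fold, while Reln, which encodes the secreted protein reelin, rose 4.29-fold. The camera call of this list was lost over genes with a mean of at least 5 CPM (adjusted p = 0.0614) and without rescaling (0.207, the highest of 19 other settings, which began at 0.000349). Map2, the most abundant member, was 1.24-fold lower. Its log2 fold change stayed at -0.31, but the call was lost when either Pten/p53 line was left out (adjusted p = 0.159 and 0.166 in limma), with no filter on low genes (0.0625) and with a single prior variance (0.0571).

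Markers of stem and progenitor states went both ways, and at the main settings camera called none of these lists. The counts adjusted over the list alone were the same as those over all genes for each of them. Of 19 neural stem cell markers 8 rose and 6 fell (camera, adjusted p = 0.764): Prom1, which encodes CD133, fell from 15.6 ± 0.384 to 0.118 ± 0.0370 CPM, the intermediate filament gene Nes fell 2.45-fold and Id3 2.76-fold, while Notch1 rose 2.63-fold. Egfr, named after its value was seen, was at 948 ± 32.7 and 1078 ± 66.2 CPM (limma, adjusted p = 0.115), and passed at a log2 fold change of -0.22 without Idh1/Pten/p53 replicate 2 (limma, adjusted p = 0.0218) and at -0.95 without rescaling. Of 12 oligodendrocyte progenitor markers 7 rose and 5 fell (camera, adjusted p = 0.764), with Nkx2-2 up 4.33-fold and Sox8 up 2.21-fold, and C1ql1 down 12-fold besides Vcan. Oligodendrocyte markers (5 higher, 3 lower of 10) and proneural glioma genes (9 higher, 5 lower of 16) gave camera adjusted p of 0.515 and 0.439. In these lists Ugt8a fell 22.4-fold (16.2-fold and 36.1-fold with either Idh1/Pten/p53 line left out), Mal rose from 0.058 ± 0.017 to 1.42 ± 0.208 CPM (5 reads to 95), and Rab33a fell from 20.4 ± 1.71 to 0.197 ± 0.156 CPM, and Ncam1, a neural adhesion molecule, rose 3.34-fold and the neuronal stathmin gene Stmn4 fell 4.53-fold. Of 21 mesenchymal glioma genes 13 rose and 6 fell (camera, adjusted p = 0.0961), including rises of 23.8-fold for the receptor gene Met, 23.1-fold for the integrin gene Itga5, 39.3-fold for Anxa1 and 16.5-fold for Anxa2. This list was called in 4 of 19 other camera settings (adjusted p from 4.97e-05 to 0.147): at a mean of at least 5 CPM (0.00701), on the ranked statistic (0.000349), without rescaling (4.97e-05) and without Pten/p53 replicate 2 (0.0445).

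Regional identity genes differed as well. Of 38 Hox genes, the patterning factors of the hindbrain and trunk, 10 passed the filter on low genes. All 10 rose, also adjusted over the list alone (camera, adjusted p = 4.34e-05, and 0.433 with an estimated correlation). Hoxa10 and Hoxd3 passed that filter only through the Idh1/Pten/p53 lines, so their rise follows in part from the filter. Hoxa3 and Hoxa5 rose 16.4-fold and 16.6-fold, each from 1.3 to 21.8 CPM, with SDs of up to 1.35 CPM, and Hoxa10 from 5 reads to 449. Hoxd3, with 0 reads in the Pten/p53 libraries and 328 in the others, was at least 141-fold higher. The forebrain regional transcription factors were divided, with 7 higher and 9 lower of 19 (8 and 9 adjusted over the list alone; camera, adjusted p = 0.764). Within that list Nr2f2 rose 30.3-fold and Sp8 90.3-fold to 11.4 ± 0.631 CPM (62.5-fold and 163-fold with either Pten/p53 line left out), Zic1 fell 13.7-fold, and Lhx8, with 0 reads against 586, was at least 151-fold lower. Of 19 imprinted genes 13 fell and 3 rose, also adjusted over the list alone (camera, adjusted p = 0.0285; adjusted p = 0.466 with an estimated correlation). Nnat, which encodes neuronatin, fell 54.0-fold, from 156 ± 10.5 to 2.88 ± 0.13 CPM, Peg12 fell 9.75-fold and Mest 6.00-fold. The amino acid transporter gene Slc38a4, with 0 reads against 418, was at least 108-fold lower. The camera call of the imprinted list was lost in 4 of 19 other settings (adjusted p from 0.000349 to 0.127): with no filter on low genes (0.127), at a mean of at least 5 CPM (0.109), on voom values (0.0536) and without rescaling (0.117).

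Lipid synthesis genes fell together. In the cholesterol and fatty acid synthesis list 26 of 29 members fell and 1 rose, also adjusted over the list alone (camera, adjusted p = 2.33e-06; adjusted p = 0.587 with an estimated correlation). The isoprenoid enzyme gene Idi1 fell 5.69-fold, the last enzyme of cholesterol synthesis, Dhcr7, 6.78-fold, the cholesterol carrier gene Stard4 5.65-fold and the fatty acid elongase gene Elovl6 4.27-fold. Fatty acid synthase, Fasn, fell 3.56-fold, from 2417 ± 66.1 to 679 ± 79.1 CPM. The desaturase gene Scd2 was 1.28-fold lower, a call lost when either Pten/p53 line was left out (log2 fold changes of -0.39 and -0.32 against -0.35 with all; adjusted p = 0.0889 and 0.144 in limma).

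Other metabolic lists, and those closest to the chemistry of mutant Idh1, were not called by camera at the main settings. Of 24 TCA cycle and 2-hydroxyglutarate genes 4 rose and 11 fell (4 and 9 adjusted over the list alone; camera, adjusted p = 0.2). D2hgdh, the dehydrogenase that removes D-2-hydroxyglutarate, rose 4.54-fold, from 1.88 ± 0.338 to 8.52 ± 0.941 CPM, while the mitochondrial isocitrate dehydrogenase gene Idh2 fell 1.89-fold, Fh1 1.81-fold and Suclg2 1.78-fold. L2hgdh, the counterpart for the L form, named after its value was seen, fell 1.75-fold. Of 32 dioxygenases that use 2-oxoglutarate 17 rose and 8 fell after rescaling and 3 rose and 19 fell without it (camera after rescaling, adjusted p = 0.124), and this list was called at a mean of at least 5 CPM (0.029, the lowest of 19 other settings, which reached 0.476). The collagen lysyl hydroxylase gene Plod1 rose 3.29-fold, the DNA demethylase gene Tet3 1.81-fold and the histone demethylase gene Kdm3a 1.94-fold, and Kdm2b fell 2.19-fold. Tet3 and Kdm3a did not pass without rescaling (limma, adjusted p = 0.52 and 0.272). Of 18 DNA methylation and Polycomb genes 5 rose and 4 fell (camera, adjusted p = 0.825), with the maintenance methyltransferase gene Dnmt1 down 3.51-fold, its partner Uhrf1 down 3.73-fold, and Jarid2 and Ezh1 up 2.13-fold and 2.15-fold. Glutamate and branched-chain amino acid genes (14 higher, 7 lower of 26; camera, adjusted p = 0.201) included rises of Abat (4.26-fold), Bckdha (3.96-fold) and Glud1 (2.25-fold) and a 3.47-fold fall of Gad1. Hypoxia and HIF target genes (8 higher, 13 lower of 27, median log2 fold change -0.57; camera, adjusted p = 0.693) included falls of Hk2 (2.99-fold) and Ndrg1 (4.15-fold), named after their values were seen, and rises of Ero1l (5.22-fold), Ddit4 (4.86-fold), Mxi1 (4.07-fold) and Vegfa (3.09-fold). NRF2 target genes (6 higher, 10 lower of 18; camera, adjusted p = 0.577) included a 3.41-fold rise of Gstm1 and a fall of Nqo1 from 7.07 ± 0.287 to 0.911 ± 0.186 CPM. In the lists of this paragraph after the first, the counts adjusted over the list alone were the same.

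Stress response genes rose and feedback genes of the ERK pathway fell. In the integrated stress and unfolded protein response list 14 of 20 members rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.00242; adjusted p = 0.559 with an estimated correlation). Atf5 rose 8.07-fold, Ppp1r15a 3.62-fold and the chaperone gene Dnajb9 3.10-fold, while Sdf2l1 fell 4.28-fold. Ddit3 (6.41-fold), Atf3 (16-fold) and Trib3 (8.86-fold), targets of the stress factor Atf4 named after their values were seen, rose too. With either Pten/p53 line left out, Atf3 was 29.7-fold and 11-fold higher and Trib3 16.1-fold and 6.12-fold. The amino acid transporter gene Slc3a2 rose 3.89-fold to 1342 ± 25.9 CPM and Atf4 itself, also named after its value was seen, 1.6-fold. The Pten/p53 lines differed from each other in this list, with 345 ± 101 CPM for Slc3a2 and 23.1 ± 14.7 CPM for Trib3. The calls of Slc3a2, Trib3 and Atf4 were lost when either Idh1/Pten/p53 line was left out (adjusted p of 0.0553 and 0.0571, 0.123 and 0.119, and 0.205 and 0.166 in limma), while their log2 fold changes stayed near those with all lines (2 and 1.97 against 2, 3.23 and 3.32 against 3.29, and 0.65 and 0.75 against 0.72). Atf4 also turned to -0.06 without rescaling (limma, adjusted p = 0.757). Of 15 MAPK feedback genes 13 fell and 2 rose, also adjusted over the list alone (camera, adjusted p = 0.000575; adjusted p = 0.433 with an estimated correlation). The ERK phosphatase genes Dusp4 and Dusp6 fell 12.2-fold and 3.82-fold, the inhibitor genes Spry4 and Spred3 6.68-fold and 3.43-fold, and Etv5 3.03-fold.

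Other signalling lists were mixed and not called by camera at the main settings, with counts that were the same adjusted over the list alone. Wnt target genes (9 higher, 10 lower of 22; adjusted p = 0.764) included a 24.3-fold rise of the Wnt inhibitor gene Wif1, a 3.54-fold rise of Wnt7b and a 37.0-fold fall of Sfrp1. Notch and Hedgehog genes (11 higher, 4 lower of 19; adjusted p = 0.127) included rises of Notch2 (6.17-fold) and Ptch1 (2.67-fold) and a fall of Nrarp (5.21-fold), and were called at a mean of at least 5 CPM (camera, adjusted p = 0.0286, with 0.194 the highest of 19 other settings). Immediate early genes (10 higher, 5 lower of 17; adjusted p = 0.29) included rises of Fos (4.48-fold) and Klf4 (10.8-fold) and a fall of Egr1 (5.35-fold). Receptor tyrosine kinases and growth factors (12 higher, 4 lower of 23; adjusted p = 0.201) included Fgfr2 (7.56-fold higher) and Ntrk2 (4.08-fold higher), and were called by camera on the ranked statistic (adjusted p = 0.0237, with 0.28 the highest of 19 other settings). In the PI3K and FoxO list (13 higher, 4 lower of 23; adjusted p = 0.138) Sesn3, Foxo3 and Pink1 rose 4.08-fold, 3.42-fold and 2.89-fold, and Trib2 fell 2.34-fold.

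Interferon-stimulated genes rose: 20 of 25 were higher and 3 lower, also adjusted over the list alone (camera, adjusted p = 0.000166; adjusted p = 0.433 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, rose 5.15-fold, Gbp2 22.5-fold to 8.55 ± 1.07 CPM and Stat1 2.30-fold, while Ifit2 fell 3.89-fold. The camera call of this list was lost at a mean of at least 5 CPM (adjusted p = 0.0792, the highest of 19 other settings, which began at 4.1e-09). Of 12 antigen presentation genes 9 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.0285; adjusted p = 0.466 with an estimated correlation). This call was lost in 5 of 19 other settings at the preset correlation (adjusted p from 0.00168 to 0.237): at a mean of at least 5 CPM (0.237), on voom values (0.0686), on the ranked statistic (0.0669), without Idh1/Pten/p53 replicate 1 (0.0623) and with a pseudocount of 10 (0.0531). B2m and the peptide-loading gene Tapbp rose 2.02-fold and 2.87-fold (B2m did not pass without rescaling; limma, adjusted p = 0.0568), and Nlrc5, the class I transactivator, went from 3 reads to 129, a ratio of 55.6 (95% exact counting interval 18.6 to 273). H2-K1, a class I heavy chain gene whose sequence varies between mouse strains, fell 4.63-fold. Chemokines and cytokines (7 higher, 5 lower of 14, also adjusted over the list alone) were not called at the main settings (camera, adjusted p = 0.276), with Tgfb3, Il33, Cx3cl1 and Tgfb2 up 8.49-fold, 5.25-fold, 4.77-fold and 2.14-fold. They were called at a mean of at least 5 CPM (0.00285) and without rescaling (0.00505), with 0.36 the highest of 19 other settings. Ribosomal protein genes rose slightly relative to the median gene, with 22 of 35 higher and 0 lower, also adjusted over the list alone, but 1 higher and 26 lower without rescaling of the deposited values (camera after rescaling, adjusted p = 0.00112; adjusted p = 0.665 with an estimated correlation; adjusted p = 0.903 and lower without rescaling). Rpl30 rose 3.30-fold and Rpl8 1.84-fold, both on chromosome 15, and Rpl8 did not pass without rescaling (limma, adjusted p = 0.376).

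**Figure D3:**
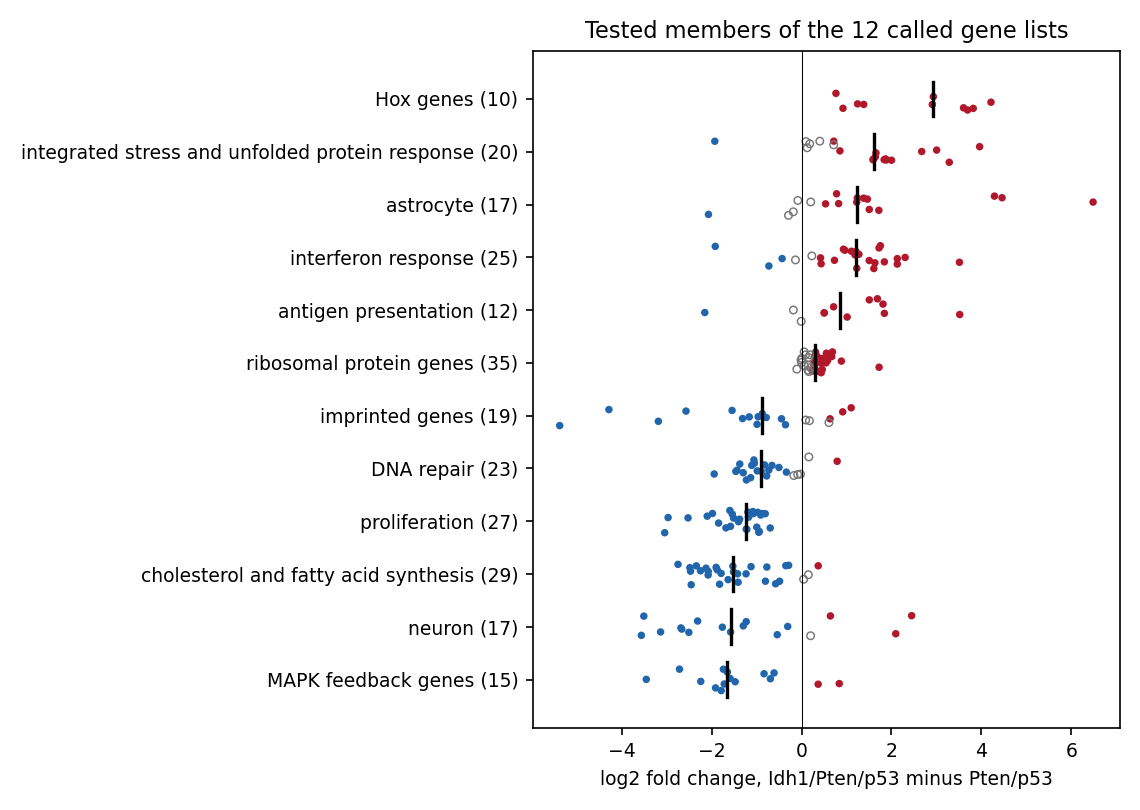
Log2 fold changes (horizontal axis, Idh1/Pten/p53 minus Pten/p53, limma after rescaling) of the tested members of the 12 lists called by camera at its preset correlation, with member numbers in parentheses and a bar at each median. Filled points passed the gene test and open points did not, and all 27 proliferation genes lie to the left of 0 and all 10 Hox genes to the right, while 22 of the 35 ribosomal protein genes passed on the right and 0 on the left, against 1 and 26 without rescaling.

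Most markers of microglia, vessel, ependymal and fibroblast cells were scarce. Of 15 microglia and macrophage markers, 14 stayed under 1 CPM in all 4 libraries, and the 2 that could be tested did not pass. Also under 1 CPM in all 4 were 11 of 14 endothelial and pericyte, 8 of 10 ependymal and 9 of 15 fibroblast and smooth muscle markers. The endothelial and pericyte list had 4 tested members, of which the vascular receptor gene Kdr fell from 9.43 ± 1.04 to 0.793 ± 0.471 CPM and Pecam1 rose from 0.299 ± 0.00500 to 1.13 ± 0.132 CPM. The ependymal list had 4 tested members, of which Hydin fell from 18.8 ± 0.299 to 10.9 ± 0.76 CPM. Fibroblast and smooth muscle markers (5 higher, 2 lower of 8) were not called (camera, adjusted p = 0.187; called without rescaling at 0.00251, with 0.256 the highest of 18 other settings), and in each of these 4 lists the counts were the same adjusted over the list alone. Thy1 rose from 0.0570 ± 0.0150 to 23.1 ± 1.17 CPM and Col6a1 6.20-fold, while Myl9 fell 6.29-fold. Among the haemoglobin list only Alas2 was tested and it did not pass, and the globin genes held 1 read in all libraries together. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 65.8 ± 4.04, 81.6 ± 2.51, 50.8 ± 1.23 and 34.1 ± 0.569 CPM in the Pten/p53 lines, while the Idh1/Pten/p53 lines held 4, 4, 10 and 3 reads of them in total. For Uty this is a ratio of 764 (95% exact counting interval 261 to 3710). All reads of Eif2s3y, Kdm5d and Uty in these lines lie in replicate 1: for Uty the ratio of mean CPM is 741 with all libraries and 371 without replicate 2, and without replicate 1 no read is left.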

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

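The deposited values without rescaling, other pseudocounts, a single prior variance, thinned reads, log2 CPM of the recovered reads and leaving out chromosomes X and Y were chosen after the data were seen; camera on voom values had been planned, and its use on recovered reads was not. The number of genes changed was 9503, and over the other settings with the same threshold it ran from 7410 to 10738; leaving out 1 library at a time gave 7410 to 9813 (3615 to 4690 higher, 3795 to 5166 lower), where the lone line is assumed to vary like the other arm. A required change of at least 2-fold left 3368 genes, 1626 higher and 1742 lower, by construction. Without rescaling, 1571 genes were higher and 9167 lower, which follows from the median shift of -0.74 in values that still carry depth. There Pten passed at -0.74 (adjusted p = 0.00352 in limma), which equals that shift, and Trp53 at -0.92. Atf4 turned to -0.06 and lost its call (limma, adjusted p = 0.757). Pten ranged from -0.07 to 0.12 and Trp53 from -0.36 to -0.06 when each library was left out in turn, and Idh1 from -1.29 to -1.22. Camera called 12 lists at the main settings and 10 on voom values. With an estimated correlation it called 0, and 2 reached an unadjusted p under 0.05. That correlation is poorly known with 2 libraries per genotype. It lay under the preset 0.01 for the MAPK feedback, astrocyte, DNA repair, interferon, Hox, neuron, imprinted and antigen presentation lists (-0.045 to -0.004). A higher correlation therefore did not remove those calls, and their loss does not show that co-regulation explains them. The estimate lay above 0.01 for the proliferation, cholesterol, integrated stress and ribosomal protein lists (0.285 to 0.778). At a mean of at least 5 CPM camera called 11 lists. There neuron (0.0614), imprinted (0.109), interferon (0.0792) and antigen presentation (0.237) genes lost the call, and Hox genes had too few members. Mesenchymal (0.00701), dioxygenase (0.029), Notch and Hedgehog (0.0286) and chemokine (0.00285) genes gained it. The proliferation, cholesterol, MAPK feedback, DNA repair, integrated stress and astrocyte lists kept their call in all 19 other camera settings at the preset correlation, and the Hox list in the 18 it entered; fry, which does not compare a list with other genes, called 29 by direction and 33 in mixed direction. The gap in Spearman correlation within and between genotypes was 0.081, and 1.188 over the 500 most variable genes, by construction. Counting each named gene under each other setting, 3085 values kept direction and side of the threshold, 18 lost the call and 4 gained it in the same direction, and 4 turned: Pten when Idh1/Pten/p53 replicate 2 or Pten/p53 replicate 1 was left out, and, without rescaling, Pten, which gained a call, and Atf4, which lost one. The replicate number as a block gave 9437 changed genes, with 9305 of the 9503 kept in the same direction, and 12 lists. Same-numbered lines did not deviate together over genes (correlation 0.00). With 2 libraries per genotype this cannot tell whether they share a day or a preparation. The planned quasi-likelihood and DESeq2 count fits were not run, since the deposited values are not counts. Depth limits genes that did not reach about 0.26 CPM in at least 2 libraries, which were not tested.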

Other observations

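Neurotransmitter receptor genes, a group chosen after Grik3 and Gabra3 had been seen among the most changed genes, were mostly lower in the Idh1/Pten/p53 lines. The count took glutamate receptor genes named Gria, Grik, Grin or Grm and GABA receptor genes named Gabr, and holds no other receptor genes. Of these 27 tested genes, 20 fell and 5 rose, and 7 fell at least 8-fold, Grik3 and Gabra3 among them. Without the 2 genes that prompted the count, 18 of 25 fell (72%), against 36.6% of all tested genes (Fisher's exact test over genes, two-sided p = 0.000513; genes are not independent replicates). The NMDA receptor gene Grin2c fell from 36.7 ± 3.37 to 0.775 ± 0.0750 CPM and the kainate receptor gene Grik1 from 22.5 ± 1.87 to 0.611 ± 0.0470 CPM (SD, n = 2), while Grik2 rose from 19 to 39.2 CPM.

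The receptor test above was chosen after the result was seen. The tests below had their bounds written before their values were seen, except that the comparisons of the X-linked genes with random sets, of the Idh1 region with its bootstrap error and of the chromosome sides with shuffled genes were made part of the bounds afterwards. Genes of several chromosomes shifted together, which was seen before the test by position along the chromosome was set up. The median log2 fold change was 0.42 on chromosome 15, 0.31 on 6 and 19, 0.26 on 8, -0.12 on 9, -0.15 on 11 and -0.44 on X (permutation of genes over chromosomes, adjusted p of 0.0014 for 9 and 0.00033 for the others, whose unadjusted p of 1e-04 is the smallest the permutations can give). On 6 of these 7 chromosomes the genes on either side of the middle gene had both moved by at least 0.1 in one direction, the exception being 11 (-0.23 and -0.07). This count follows largely from choosing chromosomes by their medians: shuffling genes within each chromosome, added after the count was seen, gave 6 or more in 89.8% of 1000 shuffles (mean 6.3). It therefore cannot tell whole-chromosome gain or loss, a candidate explanation for which a step from 3 to 4 copies would give 0.42, from scattered changes. DNA copy number was not analysed here, and the shifts are hypotheses from transcript levels alone.

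Very large changes also tended to lie next to each other. Neighbouring tested genes that both changed at least 8-fold in one direction formed 16 pairs, against a mean of 6.5 in 10000 shuffles of gene positions (one-sided permutation p = 0.001). Neighbours follow the order of the tested genes and can lie far apart, as Tenm1 and Smarca1 do on X (42527866 to 47892974). Deleted or silenced segments may account for some pairs, such as Rprm with Galnt13 on chromosome 2 (54084093 to 55118309) or Tenm1 with Smarca1. Neighbours under shared control, such as Irx1 with Irx2 or S100a1 with S100a13, would give the same count, so the test does not separate these.

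The first pattern weighed is that most tested genes differed, and depth does not account for it, since thinning all libraries to the smallest left 9445 genes called. Nor do average shifts of the genes on whole chromosomes, since 9378 genes were called after each chromosome's median was removed. Effects of a gained or lost chromosome on genes elsewhere were not tested and stay open. The real split of the 4 libraries gave 9503 genes, and the highest of the other splits gave 0 in limma (2 genes at an unadjusted p under 0.05). The other splits mix the genotypes in both arms, so the gap between genotypes counts there as spread within an arm. Few calls would follow whatever caused the gap, and 3 splits are too few for a share under 0.05. No conclusion is drawn from the splits. Differences between the lines other than Idh1, such as founder animal, inherited strain segments or changes in culture, cannot be told apart from the effect of Idh1, because genotype and line coincide and the Spearman gap between them is 0.081 with no line of mixed state. Sex stays open too: 95.2% of the genes changed at least 2-fold lie on autosomes, but with 469 tested genes on X and Y that share could not be under 86.1%, and effects of sex on autosomal genes were not tested.

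The second is that Y-linked transcripts were nearly confined to the Pten/p53 lines. Either the lines came from mice of different sex or the Idh1/Pten/p53 cells may have lost the Y chromosome. The 4 genes known to escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) had a median log2 fold change of -0.09. The median of 459 other X-linked genes was -0.48. The difference of 0.40 had the direction expected for female cells, but it arose because the other X-linked genes were lower. The median of the 4 escape genes was not raised in the Idh1/Pten/p53 lines. They ranged from -0.33 to 0.75, however, and a permutation test on random sets of 4 X-linked genes gave a one-sided p of 0.23, so the bound set beforehand was passed by less than the spread and both stay open. Xist was not analysed here.

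The third is the lower Idh1 transcript in the lines with mutant Idh1. Scaling does not account for it, as its log2 fold change was -1.20 or lower under every scaling tried. A lower copy number of the region is argued against by the 20 tested genes within 2 Mb, whose median was -0.09 (bootstrap SE 0.18, range -5.06 to 2.34). An effect of the engineered allele on its own transcript, or reads of it that are not counted, were not tested and stay open.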
